A study of Mus musculus with 6 samples.

How the data were processed

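Gene expression was measured by RNA-seq in 6 mouse samples labelled as megakaryocytes, 3 wild-type (WT) and 3 Abcc4-/-. Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced as paired-end reads. Per the submitters' processing notes, STAR 2.7 and RSEM 1.3.1 were used with the mm10 build; the annotation release is not given in the sources used here. The authors deposited 1 table of expected counts per gene, not normalized, and 1 table of TPM, scaled within each sample. Both tables are marked as stranded. They hold 55573 genes and 92 spike-in entries, all at 0 counts, which were left out. Gene positions came from the GRCm38 annotation supplied for this work, which matched 55180 genes by versioned identifier and 55480 without the version.

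Groups came from the genotype given for each sample, and replicate numbers from the sample titles. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The deposited expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, its default filter on low counts, which kept 16493 genes, and the robust quasi-likelihood test of Abcc4-/- against WT. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. CPM values used the TMM library sizes, and SE was derived from the fold change and its test statistic. The interval of the Gm26773 count ratio and the floor of 3 counts cover counting error only. Odds ratio intervals treat genes as independent, and bootstrap intervals cover the spread over list members. None of these intervals measures the spread between samples.

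The gene lists, the test and the rule for naming genes were fixed before the data were examined. The rule named Abcc4; the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap and whose mean log2 CPM was at least 1, leaving out Abcc4, sex-linked genes and gene models without a functional symbol; up to 3 members of each list with the smallest adjusted p; up to 5 called genes within 20 Mb of Abcc4; and, for a list with 0 called members, the members with the smallest p. If fewer than 5 genes had been called, the 10 with the smallest p would have been given. A few genes are not reported here, including 1 that the rule names. Other genes are said to be picked after their values were seen where they are named. The 32 lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. P-values were adjusted over the lists. In all, 24 genes are in more than 1 list. A further 10 lists were added after the data were seen. Single values were compared with exact permutation tests, where 3 against 3 cannot give a two-sided p below 0.1.

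The gene test was checked on counts simulated for the 16493 genes of this comparison, with 200 genes changed in each of 6 runs. With dispersions drawn per gene, 71.0% of 1.5-fold, 84.7% of 2-fold, 98.7% of 4-fold and 98.7% of 8-fold changes were recovered, and 7.33% to 13.6% of calls were unchanged genes. With dispersions on the trend, the shares were 72.7%, 90.3%, 99.7% and 100%, and 3.26% to 7.96% of calls were unchanged genes. With dispersions drawn per gene, the share of unchanged genes lay above the level that the adjusted p threshold aims for. The real comparison called 2852 genes, and their median absolute log2 fold change of 0.41 was below the smallest simulated change. The runs therefore do not give the recovery of such small changes, or the share of unchanged genes among the real calls. Of 120 simulated lists shifted by 0.5 on the log2 scale, 120 were called by each list test, and of 120 unshifted lists between 0 and 3. The simulated genes varied independently of each other, whereas the estimated correlation within the fixed lists reached 0.910. These list counts therefore do not show how often each test calls unshifted lists of correlated genes. Alternatives covered other normalizations, DESeq2 1.42.0, limma-voom, other filters, the replicate number as a block, the deposited TPM on log2 scales with pseudocounts of 1 and 0.1 (which understate changes of low genes), and each library left out in turn. Thinning to the smallest library total, centred TPM and a scan of windows from 0.5 to 20 Mb were chosen after seeing the data.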

Results

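RNA was sequenced from 3 wild-type (WT) and 3 Abcc4-/- mouse samples labelled as megakaryocytes, the platelet-forming cells of the bone marrow. The sample titles also contain CD41, a surface protein of these cells, and how the cells were selected is not given in the sources used here. Abcc4 encodes a membrane transporter known to export cyclic nucleotides, prostanoids and nucleotide-type drugs, the thiopurine 6-mercaptopurine among them. The title of the series names megakaryocyte formation and sensitivity to that drug. The labels of these 6 samples give a genotype and no treatment, so the comparison asks how the transcripts of these samples differ between the genotypes.

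The libraries held between 50440239 and 55123512 counts in WT and between 67009925 and 99294493 in Abcc4-/-. The Abcc4-/- libraries were deeper than each WT library, by 1.55-fold on average (n = 3 each; exact permutation test, two-sided p = 0.1, the smallest p that 3 against 3 allows). A count of 3 corresponded to between 0.0302 and 0.0595 CPM, the count scaled to a common library size. Across genes, log2 CPM correlated at 0.993 to 0.995 between libraries of the same genotype and at 0.985 to 0.990 between genotypes, where genes are not independent replicates. No library pair agreed within sampling noise (chi-square per degree of freedom at least 13.4). The largest principal component, with 50.4% of the variance, separated the genotypes. Xist was present in all 6 libraries (35760 to 62737 counts), and Ddx3y, Eif2s3y and Kdm5d had 0 counts in each.

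Granulocyte and macrophage transcripts were among the most abundant over the 6 libraries together, beside the mitochondrial mt-Co1 and the translation factor Eef1a1; these genes were picked after their values were seen. Lyz2 stood at 8542 ± 744 CPM in WT and 8847 ± 635 CPM in Abcc4-/- (SD, n = 3; edgeR, adjusted p = 0.729). S100a9 rose from 5995 ± 923 to 10339 ± 330 CPM, S100a8 from 4646 ± 725 to 8421 ± 355 CPM and Ngp from 4068 ± 556 to 6928 ± 394 CPM (edgeR, adjusted p = 0.0007, 0.00054 and 0.00039). A fixed list of 20 neutrophil genes took 3.14 ± 0.385% of the counts in WT and 4.75 ± 0.0727% in Abcc4-/-. The 28 platelet and megakaryocyte identity genes measured took 0.217 ± 0.0299% in WT and 0.139 ± 0.00465% in Abcc4-/- (SD, n = 3; exact permutation test, two-sided p = 0.1 for each list, the smallest possible). Erythroid genes took 0.110 ± 0.00483% and 0.109 ± 0.0126% (exact p = 0.9).

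**Figure D1:**
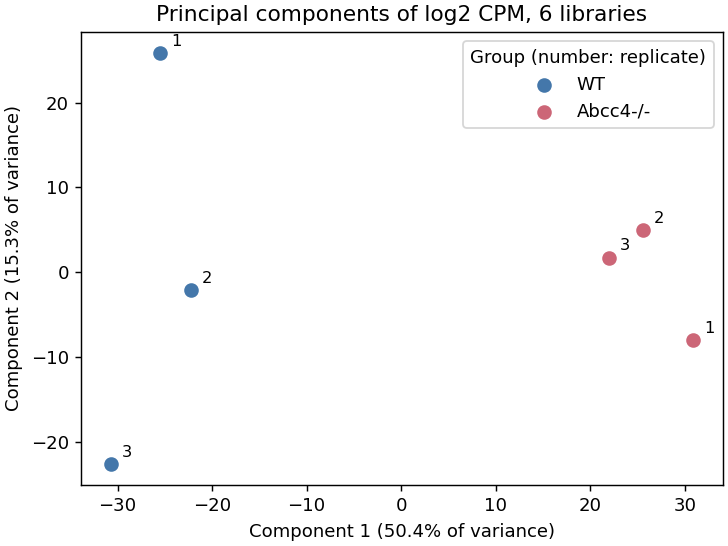
Principal components of log2 CPM for the 6 libraries, with the score on component 1 (50.4% of the variance) on the x axis and on component 2 (15.3%) on the y axis, coloured by genotype and numbered by replicate. The 3 WT libraries sit between -30.7 and -22.3 on component 1 and the 3 Abcc4-/- libraries between 22.0 and 30.9.

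Abcc4 itself was lower in all 3 Abcc4-/- libraries, and most of its transcript signal was still counted. Abcc4 (ENSMUSG00000032849.14, chromosome 14, positions 118482692 to 118706219 on the minus strand of GRCm38) had 73.9 ± 1.96 CPM in WT and 61.0 ± 1.13 CPM in Abcc4-/- (SD, n = 3). This was 82.5% of the WT level (log2 fold change -0.28, SE 0.05; edgeR quasi-likelihood test, adjusted p = 0.0026). In the deposited TPM, a measure scaled by transcript length and library total, Abcc4 stood at 19.4 ± 0.959 and 15.0 ± 0.498. The values cover the whole gene, and the deleted part of the allele is not given in the sources used here. A transcript that lacks a short segment or carries a stop codon would still be counted, so these values do not check the genotype labels.

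Many genes differed between the groups, mostly by small amounts. Of 16493 genes tested, 2852 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 1420 higher and 1432 lower in Abcc4-/-. The median absolute log2 fold change of these genes was 0.41. Large changes were mostly decreases: 292 genes fell and 183 rose at least 2-fold, and 72 fell and 9 rose at least 4-fold. The groups did not overlap for 6065 genes (36.8%, where chance gives 10%), and 5092 genes had an unadjusted p below 0.05. Without Abcc4-/- replicate 1 the count was 1821, and without Abcc4-/- replicate 2 it was 1760. The balance of directions depended on the scaling: limma on log2(TPM + 1) gave 599 higher and 1512 lower (28.4% higher, against 49.8% in the count test), with the median of all genes at -0.06. With each library centred on its median TPM value, it gave 1134 higher and 856 lower (57.0%). Calls of named genes that ended on these scales or on log2(TPM + 0.1) are given with the genes.

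Among called genes with a mean log2 CPM of at least 1, genes of early lymphoid cells and T cells were among the 10 largest increases, and stress-inducible and inflammatory genes among the 10 largest decreases. Rag2, which cuts antigen receptor genes for recombination, rose 3.42-fold (2.61 ± 0.420 to 8.95 ± 1.23 CPM, adjusted p = 1.9e-05). The surrogate light chain genes Vpreb1 and Igll1 rose 3.28-fold and 3.04-fold (adjusted p = 0.0004 and 0.0017). The T cell receptor component Cd3e rose 3.22-fold (1.31 ± 0.220 to 4.21 ± 0.472 CPM, adjusted p = 3.6e-05), and the chemokine receptor gene Cxcr6 rose 3.56-fold (adjusted p = 0.00071). Prok2 and Steap4 rose 3.30-fold and 2.82-fold (adjusted p = 0.0065 and 0.0185). Immunoglobulin variable segments were also among the 10 largest increases, Ighv7-1 (log2 fold change 1.85), Igkv5-43 (1.52) and Igkv15-103 (1.49), and Igkv5-39 was among the 10 largest decreases (-3.33). These segments have near-identical copies that can share reads, so their values are uncertain.

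The stress-inducible transcription factor gene Atf3 fell from 393 ± 63.6 CPM in WT to 19.6 ± 7.12 CPM in Abcc4-/- (20.2-fold, log2 fold change -4.34, edgeR adjusted p = 0.0032). Maff, another transcription factor gene, fell 16.4-fold (adjusted p = 0.0032). The nuclear receptor genes Nr4a1 and Nr4a2 fell 7.87-fold and 6.55-fold (adjusted p = 5.5e-06 and 7.7e-07). The kinase gene Plk2 fell 6.59-fold (adjusted p = 0.0017) and the lymphocyte activation marker Cd69 fell 8.16-fold (adjusted p = 0.0083). The chemokine gene Ccl4, the cytokine gene Il6 and the NF-kB inhibitor gene Tnfaip3 fell 9.82-fold, 8.71-fold and 7.23-fold (adjusted p = 0.0094, 0.0145 and 0.0118). Several of these 20 genes lost their call without 1 library: Il6 without any Abcc4-/- replicate (adjusted p = 0.0539 to 0.0710), Tnfaip3 without Abcc4-/- replicate 2 or 3 (0.0595 to 0.0600) and Ccl4 without Abcc4-/- replicate 3 (0.0507). Steap4 lost it without any WT replicate (adjusted p = 0.0648 to 0.0950), Igkv15-103 without WT replicate 3 (0.0800), and Igkv5-43 without WT or Abcc4-/- replicate 3 (0.0715 to 0.0842). Ighv7-1 lost it without any library but WT replicate 2 and Abcc4-/- replicate 2 (adjusted p = 0.0685 to 0.142), and Igkv5-39 without any but WT replicates 1 and 2 (0.0864 to 0.145). Ighv7-1 lost its call on each TPM scale (adjusted p = 0.0592 to 0.0694), and Igkv5-39, Ighv7-1 and Igkv5-43 with at least 1 other count test, scaling, depth or filter (0.0504 to 0.0991).

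**Figure D2:**
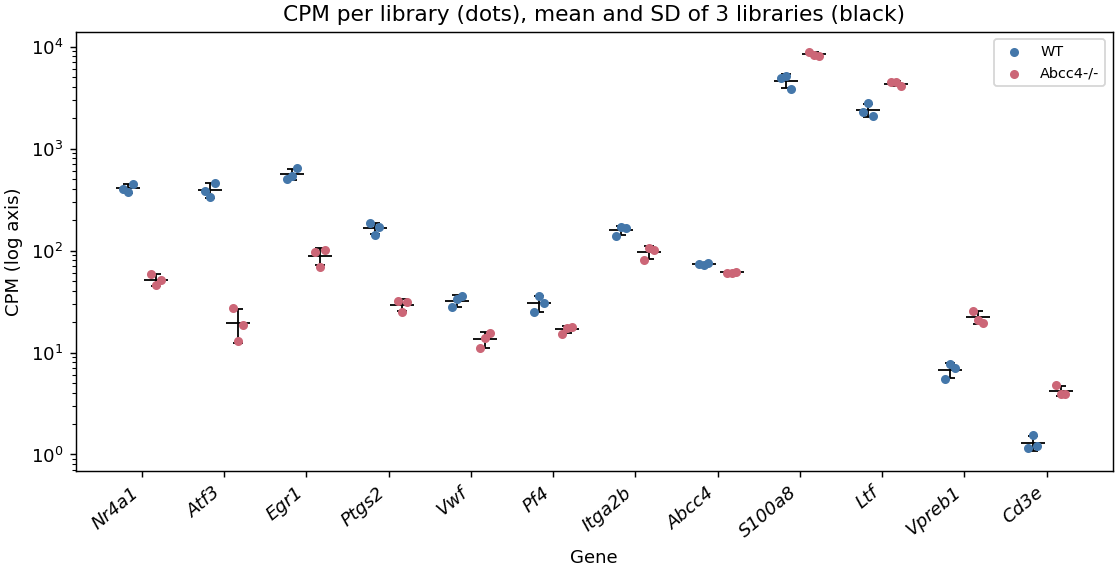
CPM on a log axis for 12 genes, some picked after their values were seen, with a dot per library (WT blue, Abcc4-/- red) and black marks for the mean and SD of 3 libraries. Nr4a1, Atf3, Egr1, Ptgs2, Vwf, Pf4, Itga2b and Abcc4 are lower and S100a8, Ltf, Vpreb1 and Cd3e higher in Abcc4-/-.

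The immediate early genes fell nearly throughout. In the list of 27 CREB-responsive and immediate early genes, which are switched on within minutes by cAMP and other signals, 24 fell and 0 rose (25 fell when adjusted over the list alone), with a median log2 fold change of -1.50. The kinase gene Sik1 fell 3.31-fold (306 ± 16.1 to 92.4 ± 3.28 CPM, adjusted p = 4.1e-08), Ier2 2.18-fold (adjusted p = 7.7e-07) and the zinc finger gene Egr1, picked after its value was seen, 6.33-fold (adjusted p = 0.00072). The list as a whole was lower (camera with a preset correlation, adjusted p = 3e-23; adjusted p = 0.321 with an estimated correlation; fry, adjusted p = 0.00078). It took 1.33 ± 0.0364% of the counts in WT and 0.50 ± 0.0413% in Abcc4-/- (exact p = 0.1, the smallest possible). The list shares 4 members with other lists (Crem, Btg2, Ier3 and Pde4b).

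NF-kB targets and inflammatory cytokines were lower as well. Of 27 genes measured, 14 fell and 0 rose (15 fell when adjusted over the list alone), with a median log2 fold change of -1.03. Ptgs2, the inducible cyclooxygenase that starts prostaglandin synthesis, fell 5.65-fold (166 ± 21.9 to 29.4 ± 3.84 CPM, adjusted p = 8.6e-05), Ier3 3.91-fold (adjusted p = 0.00025) and the NF-kB modulator gene Nfkbid 2.59-fold (adjusted p = 2.1e-05). The list was called lower by camera (adjusted p = 2.1e-08; adjusted p = 0.321 with an estimated correlation) and by fry (adjusted p = 0.0025). It shares 5 members with other lists (Il6, Ccl3, Ptgs2, Birc3 and Ier3). Il6 lost its call without any Abcc4-/- replicate (adjusted p = 0.0539 to 0.0710), Tnfaip3 without Abcc4-/- replicate 2 or 3 (0.0595 to 0.0600) and Ccl4 without Abcc4-/- replicate 3 (0.0507).

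Platelet receptor and megakaryocyte identity genes were mostly lower in Abcc4-/-. Of 28 measured, 17 fell and 2 rose (19 and 3 when adjusted over the list alone), with a median log2 fold change of -0.47. Vwf, the platelet adhesion protein stored in alpha granules, fell 2.39-fold (32.2 ± 4.07 to 13.5 ± 2.29 CPM, adjusted p = 0.002). The granule-trafficking gene Rab27b fell 1.87-fold (adjusted p = 0.00034) and the thrombin receptor gene F2rl2 1.55-fold (adjusted p = 0.0039). Other genes were picked after their values were seen: the platelet factor gene Pf4 fell 1.81-fold (30.5 ± 5.67 to 16.8 ± 1.37 CPM, adjusted p = 0.0066), and the genes that rose were Cd9 (1.16-fold, adjusted p = 0.0092) and Ppbp (1.48-fold, adjusted p = 0.0273). The surface integrin gene Itga2b, which encodes the CD41 that the sample titles name, fell 1.64-fold (158 ± 17.3 to 96.1 ± 13.8 CPM, adjusted p = 0.0106). The list was called lower by camera (adjusted p = 2e-05; adjusted p = 0.568 with an estimated correlation) and by fry (adjusted p = 0.0373), and 4 of its members are in other lists. Itga2b lost its call without WT replicate 3 (adjusted p = 0.0667), Cd9 without Abcc4-/- replicate 2 (0.0501), and Ppbp without any library but WT replicate 1 and Abcc4-/- replicate 1 (0.0609 to 0.115). Cd9 and Ppbp lost their calls on at least 1 TPM scale (adjusted p = 0.0672 to 0.0979), and Itga2b and Ppbp with at least 1 other count test, scaling, depth or filter (0.0504 to 0.0564). Neutrophil transcripts took 3.14% of the counts in WT and 4.75% in Abcc4-/- in the same libraries, and these identity genes 0.217% and 0.139%. A lower share of megakaryocytes among the cells would lower these genes too. Counts of whole samples cannot tell this from lower expression in each cell. Which cells the transcripts of this and the following lists came from was not measured.

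**Figure D3:**
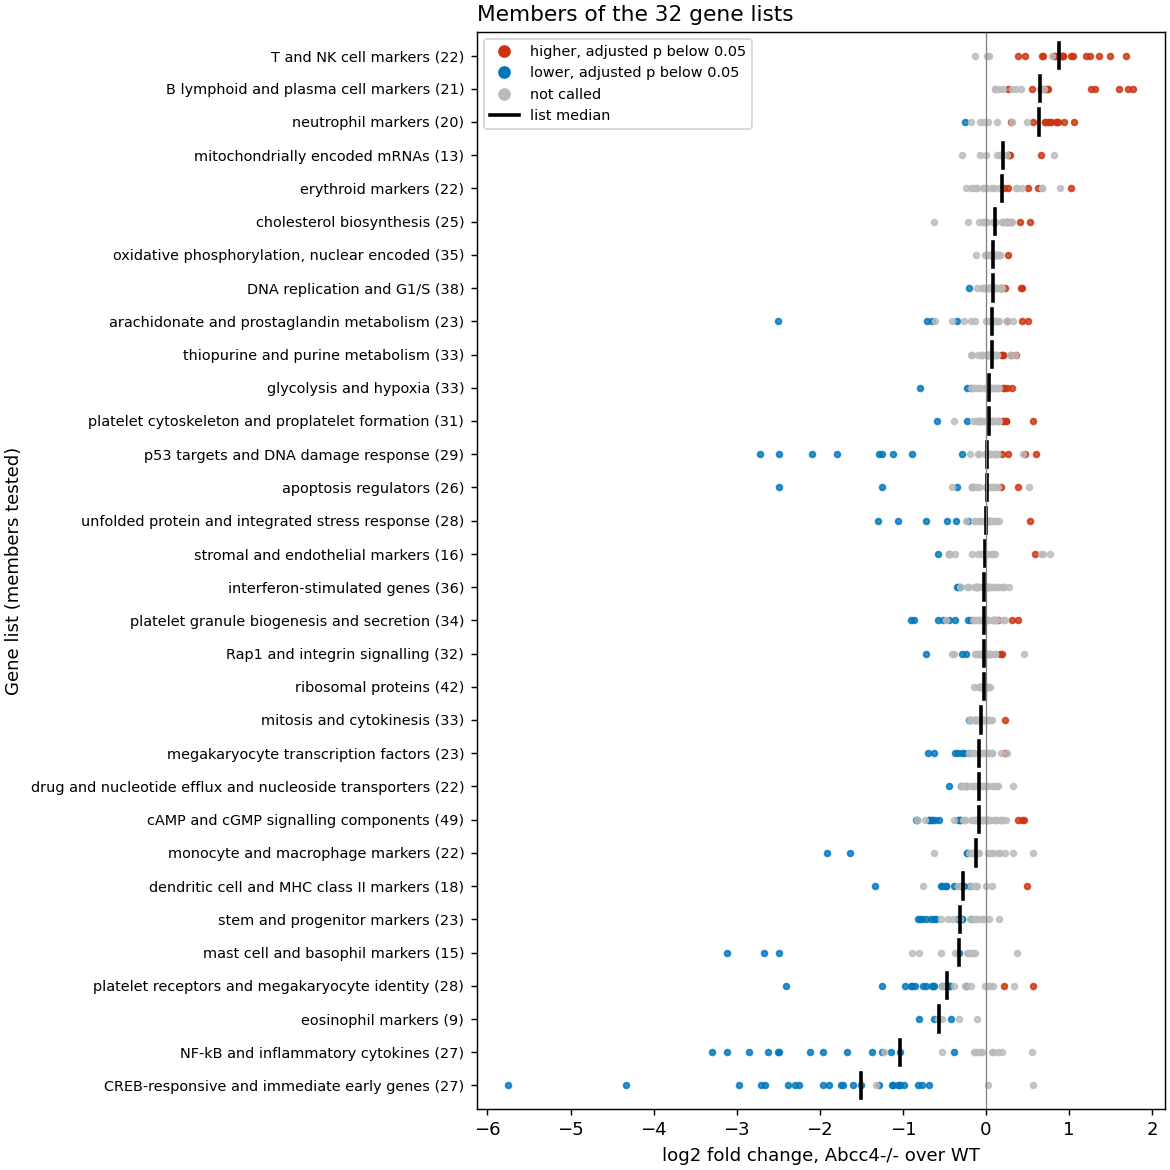
Log2 fold change (Abcc4-/- over WT, x axis) of each tested member of the 32 fixed gene lists (y axis, number of members in brackets). Dots are genes, red where higher and blue where lower at an adjusted p below 0.05 and grey where not called, and black bars are list medians, which run from -1.50 for immediate early genes to 0.88 for T and NK cell markers.

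Among 23 megakaryocyte transcription factors, 7 fell and 1 rose (8 and 3 when adjusted over the list alone). Etv6 fell by 0.37 on the log2 scale (adjusted p = 0.00052), Meis1 1.54-fold (adjusted p = 0.0012) and Srf, which drives cytoskeletal genes, 1.23-fold (adjusted p = 0.0015). Nfe2, a driver of platelet release, was the gene that rose (1.17-fold, adjusted p = 0.0191, picked after its value was seen), and lost its call without Abcc4-/- replicate 1 or 2 (0.0589 to 0.0854) and on each TPM scale (0.0528 to 0.0760). The list did not pass (median log2 fold change -0.08; camera, adjusted p = 0.0575), though it did without WT replicate 1 (adjusted p = 0.0422) or Abcc4-/- replicate 2 (0.0217), on log2(TPM + 1) (0.0148) and on centred TPM (0.0077).

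Of 34 genes of platelet granule formation and secretion, 8 fell and 3 rose (10 and 4 when adjusted over the list alone). The secretory vesicle gene Vamp2 fell 1.49-fold (85.5 ± 1.65 to 57.6 ± 2.14 CPM, adjusted p = 2.5e-05) and the granule proteoglycan gene Srgn 1.36-fold (adjusted p = 0.00023). Stx11 and Hps6 rose (log2 fold changes 0.38 and 0.31, adjusted p = 0.00082 and 0.0089), as did Rab27a (1.11-fold, adjusted p = 0.0487), which lost its call without any of the 6 libraries (0.0648 to 0.150). The list did not pass (camera, adjusted p = 0.316). Of 31 cytoskeleton and proplatelet genes, 5 rose and 2 fell (5 and 3 when adjusted over the list alone), with a list median of 0.04 that turned to -0.04 on log2(TPM + 1) but not on centred TPM (0.05; camera, adjusted p = 0.366 on counts). Actn1 rose 1.48-fold (137 ± 15.9 to 203 ± 13.6 CPM, adjusted p = 0.002) and Tpm4 1.18-fold (adjusted p = 0.0128). The others were Capza1, Wdr1 and Pfn1, higher, and Tuba8 and Mylk, lower, and all 5 lost their calls without some libraries (adjusted p = 0.0520 to 0.165). These were WT replicate 2 and Abcc4-/- replicate 1 for each gene but Pfn1, with Abcc4-/- replicate 2 for Wdr1, Abcc4-/- replicate 3 for Tuba8, and WT replicate 3 and Abcc4-/- replicate 2 for Mylk. For Pfn1 it was any library but WT replicate 2. Hps6, Rab27a, Tpm4, Capza1, Wdr1, Pfn1, Tuba8 and Mylk lost their calls on at least 1 TPM scale (adjusted p = 0.0577 to 0.580), and Rab27a, Pfn1 and Mylk with at least 1 other count test, scaling, depth or filter (0.0503 to 0.114). Stx11, Hps6, Rab27a, Wdr1, Pfn1, Tuba8 and Mylk were picked after their values were seen.

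Most of the components of cyclic nucleotide signalling that passed were lower. Of 49 genes, 11 fell and 3 rose (14 and 4 when adjusted over the list alone), with a median log2 fold change of -0.09. The prostaglandin E2 receptor gene Ptger4 fell 1.56-fold (60.2 ± 3.89 to 38.5 ± 0.635 CPM, adjusted p = 2.6e-05) and the adenylyl cyclase gene Adcy6 1.48-fold (adjusted p = 0.0008). Ptgir, the prostacyclin receptor gene, rose 1.35-fold (21.1 ± 1.12 to 28.6 ± 1.68 CPM, adjusted p = 0.001), and the others that rose, named after their values were seen, were Vasp and Pde2a. The list was called lower by camera (adjusted p = 0.0393; adjusted p = 0.568 with an estimated correlation) and by fry (adjusted p = 0.0425), and lost its camera call without WT replicate 3 (0.0725) or Abcc4-/- replicate 1 (0.0653). It shares 5 members with other lists.

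Few of the other drug and nucleotide transporters passed. Of 22 measured, 3 fell and 0 rose (2 fell when adjusted over the list alone; camera, adjusted p = 0.173). Abcc1, a related export pump, fell 1.23-fold (84.6 ± 4.72 to 68.6 ± 1.79 CPM, adjusted p = 0.0033). Slc29a3 fell 1.18-fold (adjusted p = 0.0259) and Abcc2 1.37-fold (adjusted p = 0.0448). Slc29a3 lost its call without any library but WT replicate 2 (0.0638 to 0.0913), and Abcc2 without WT replicate 3 or Abcc4-/- replicate 1 or 2 (0.135 to 0.163). Slc29a3 and Abcc2 lost their calls on at least 1 TPM scale (adjusted p = 0.0816 to 0.473), and Abcc2 with at least 1 other count test, scaling, depth or filter (0.0551 to 0.0686).

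In the thiopurine and purine metabolism list, 5 of 33 genes rose and 0 fell (4 rose when adjusted over the list alone). The guanine deaminase gene Gda rose 1.29-fold (446 ± 25.1 to 573 ± 56.4 CPM, adjusted p = 0.0065) and the AMP deaminase gene Ampd3 1.23-fold (adjusted p = 0.0095). The others were Nme1, Rrm2 and Ppat, of which the last pair was named after their values were seen, and all lost their calls without some libraries (adjusted p = 0.0535 to 0.151). These were WT replicate 3 and Abcc4-/- replicate 1 for Nme1, those and WT replicate 2 and Abcc4-/- replicate 2 for Rrm2, and any library but Abcc4-/- replicate 2 for Ppat. Gda, Ampd3 and these 3 also lost their calls on at least 1 TPM scale (adjusted p = 0.0520 to 0.416), and Ppat with at least 1 other count test or scaling (0.0502 to 0.0916). Hprt, which activates thiopurines, and Tpmt, which inactivates them, were also named after their values were seen and did not pass (log2 fold change 0.09 and 0.08, adjusted p = 0.357 and 0.770). The list median was 0.07, -0.01 on log2(TPM + 1) and 0.08 on centred TPM, and the list did not pass (camera, adjusted p = 0.0575). It passed without WT replicate 1 (adjusted p = 0.0393) and without Abcc4-/- replicate 2 (0.0241) or 3 (0.0404).

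Markers of other bone marrow cells also differed, in both directions. Of 20 neutrophil genes, 12 rose and 1 fell (13 and 1 when adjusted over the list alone), with a median log2 fold change of 0.63. The granule genes Mmp8, Lcn2 and Ltf rose 1.80-fold, 1.92-fold and 1.83-fold (Ltf from 2378 ± 351 to 4340 ± 219 CPM; adjusted p = 2.4e-05, 0.00016 and 0.00029). Mpo, a granule enzyme of immature neutrophils, fell 1.19-fold (adjusted p = 0.0350, picked after its value was seen) and lost its call without any library but WT replicate 3 (0.0755 to 0.137) and on centred TPM (0.115). Camera called the list higher (adjusted p = 4.1e-06; adjusted p = 0.568 with an estimated correlation) and fry did not call it (adjusted p = 0.0740).

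Lymphoid marker lists were higher by both list tests. Of 22 T and NK cell genes 18 rose and 0 fell (18 when adjusted over the list alone; median log2 fold change 0.88; camera, adjusted p = 7.5e-09; adjusted p = 0.568 with an estimated correlation; fry, adjusted p = 0.0425). Lck, a T cell kinase gene, rose 1.76-fold (10.1 ± 1.19 to 17.9 ± 2.47 CPM, adjusted p = 0.0013) and the cytokine receptor gene Il2rb 2.04-fold (adjusted p = 0.0019). Of 21 B lymphoid and plasma cell genes 11 rose and 0 fell (14 when adjusted over the list alone; median 0.66; camera, adjusted p = 4.5e-08; adjusted p = 0.568 with an estimated correlation; fry, adjusted p = 0.0461), led by Rag2, Vpreb1 and Igll1.

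Of 18 dendritic cell and MHC class II genes 9 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median log2 fold change of -0.28. The antigen-presentation genes H2-Aa and H2-Ab1 fell 1.40-fold and 1.44-fold (334 ± 36.2 to 239 ± 20.6 CPM for H2-Aa; adjusted p = 0.0044 and 0.0071), and Xcr1 fell 2.52-fold from 0.817 CPM (adjusted p = 0.0049). Ly6d rose (log2 fold change 0.50, adjusted p = 0.0099, picked after its value was seen) and lost its call without WT replicate 3 (0.0625), as Xcr1 did on centred TPM (0.313). The list was called lower by camera (adjusted p = 0.00018; adjusted p = 0.568 with an estimated correlation) and by fry (adjusted p = 0.0353).

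Stem and progenitor markers were lower, with 11 of 23 fallen and 0 risen (13 fallen when adjusted over the list alone) and a median log2 fold change of -0.31. Angpt1, which encodes a vascular growth factor, fell 1.58-fold (65.1 ± 4.86 to 41.1 ± 2.80 CPM, adjusted p = 9e-05) and Bcl11a 1.26-fold (adjusted p = 0.0016). The list was called lower by camera (adjusted p = 2.3e-06; adjusted p = 0.373 with an estimated correlation) and by fry (adjusted p = 0.0091). It shares Meis1 and Flt3 with other lists.

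Of 15 mast cell and basophil genes 4 fell and 0 rose (8 fell when adjusted over the list alone; median log2 fold change -0.33). The members that fell were Ccl3 (5.62-fold), Gzmb (6.39-fold), Il6 and the IgE receptor gene Fcer1a (log2 fold change -0.33, adjusted p = 0.0209, picked after its value was seen), of which Ccl3, Gzmb and Il6 are inducible effector genes that other activated cells also make. The list was called lower by camera (adjusted p = 6.8e-05; adjusted p = 0.568 with an estimated correlation) and by fry (adjusted p = 0.0483). Gzmb lost its call without Abcc4-/- replicate 2 or 3 (adjusted p = 0.0685 to 0.0751), Fcer1a without WT replicate 2 or Abcc4-/- replicate 1 or 3 (0.0523 to 0.0869), and Il6 without any Abcc4-/- replicate (0.0539 to 0.0710). Of 9 eosinophil genes 4 fell and 0 rose (5 fell when adjusted over the list alone; median -0.57; camera, adjusted p = 0.0018; adjusted p = 0.568 with an estimated correlation; fry, adjusted p = 0.0907). They were Siglecf (1.34-fold, adjusted p = 0.0032), Prg3, Epx and Prg2. Epx lost its call without any WT replicate or without Abcc4-/- replicate 3 (adjusted p = 0.0886 to 0.108), and Prg2, picked after its value was seen, without any WT replicate or without Abcc4-/- replicate 2 (0.0838 to 0.142). Prg2 lost its call on log2(TPM + 0.1) (adjusted p = 0.0550), and Epx and Prg2 with at least 1 other count test, scaling, depth or filter (0.0526 to 0.152).

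The monocyte and macrophage list did not pass (camera, adjusted p = 0.0667; median log2 fold change -0.12), although 4 of its 22 genes fell and 0 rose (4 when adjusted over the list alone). Among those that fell, the receptor gene Cd14 was 3.76-fold lower (60.2 ± 7.78 to 16.1 ± 1.95 CPM, adjusted p = 7.5e-05). Csf1r and Adgre1, the latter picked after its value was seen, also fell 1.18-fold and by 0.23 on the log2 scale (adjusted p = 0.0313 and 0.0482). Csf1r lost its call without WT replicate 1 or Abcc4-/- replicate 1 or 3 (adjusted p = 0.0917 to 0.116), and Adgre1 without any library but WT replicate 2 (0.0652 to 0.143). It also lost its call on each TPM scale (adjusted p = 0.0649 to 0.132) and with limma-voom or a non-robust dispersion (0.0587 to 0.0606). The list passed as lower without WT replicate 2 (adjusted p = 0.0109) or Abcc4-/- replicate 1 (0.0210), with a filter of at least 1 CPM in at least 3 libraries (0.0469) and on centred TPM (0.0263).

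Of 22 erythroid genes 5 rose and 0 fell (6 when adjusted over the list alone; median log2 fold change 0.19; camera, adjusted p = 0.036; adjusted p = 0.730 with an estimated correlation; fry, adjusted p = 0.270). Car1, a red cell carbonic anhydrase gene, rose 2.04-fold (14.8 ± 2.44 to 30.2 ± 3.92 CPM, adjusted p = 0.0035), and Klf1, Epor, Hemgn and Car2 also rose, of which Hemgn and Car2 were named after their values were seen. The list call was lost without WT replicate 2 (adjusted p = 0.0712), WT replicate 3 (0.0505) or Abcc4-/- replicate 3 (0.214). Klf1 lost its call without Abcc4-/- replicate 1 (adjusted p = 0.0639), Epor without WT replicate 2 or Abcc4-/- replicate 1 or 3 (0.0676 to 0.0791), and Hemgn and Car2 without any of 5 libraries (0.0573 to 0.160), all but WT replicate 3 for Hemgn and WT replicate 1 for Car2. Of 16 stromal and endothelial markers Bgn and Pdgfrb fell and Sparc rose (1 higher and 2 lower when adjusted over the list alone; median -0.02, mean 0.02, camera adjusted p = 0.886), and each lost its call without some libraries (0.0571 to 0.118). These were WT replicate 2 and Abcc4-/- replicates 1 and 2 for Bgn, WT replicates 1 and 2 and Abcc4-/- replicate 1 for Pdgfrb, and any but WT replicate 2 and Abcc4-/- replicate 3 for Sparc. Epor, Hemgn, Car2, Bgn, Pdgfrb and Sparc lost their calls on at least 1 TPM scale (adjusted p = 0.0519 to 0.314), and Hemgn, Car2 and Sparc with at least 1 other count test, scaling, depth or filter (0.0538 to 0.0641).

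Of 38 replication and G1/S genes 6 rose and 1 fell (7 and 1 when adjusted over the list alone). The cyclin genes Ccnd3 and Ccne2 rose 1.34-fold and 1.35-fold (404 ± 26.4 to 541 ± 11.7 CPM for Ccnd3; adjusted p = 0.00081 and 0.0015), and E2f8 was lower (log2 fold change -0.20, adjusted p = 0.0350, named after its value was seen), a call that ended without any library but WT replicate 2 (0.0507 to 0.129). The list median was 0.08 (camera, adjusted p = 0.0021; adjusted p = 0.675 with an estimated correlation; fry, adjusted p = 0.0995) and turned to -0.02 on log2(TPM + 1), where the median of all genes was -0.06 and the call was lost (adjusted p = 0.0791), but not on centred TPM (0.07, adjusted p = 0.0197). Of 33 mitosis genes Ccnf rose and Cenpa and Kif23 fell (1 higher and 1 lower when adjusted over the list alone; median -0.06; camera, adjusted p = 0.0667), and the list passed as lower without WT replicate 2 (adjusted p = 0.006) or Abcc4-/- replicate 1 (0.006), on log2(TPM + 1) (0.0176) and on centred TPM (0.0367). Cenpa lost its call without Abcc4-/- replicate 2 or 3 (adjusted p = 0.0700 to 0.0937) and Kif23 without any library but WT replicate 2 (0.103 to 0.130). Ccne2, Ccnf, Cenpa and Kif23 lost their calls on at least 1 TPM scale (adjusted p = 0.0612 to 0.266), and Kif23 with at least 1 other count test, scaling, depth or filter (0.0505 to 0.0648).

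Several p53 targets fell by large factors, while others did not. Of 29 p53 target and DNA damage genes 9 fell and 4 rose (the same counts when adjusted over the list alone), with a median log2 fold change of 0.02 and a mean of -0.40. The cell cycle inhibitor gene Cdkn1a fell (log2 fold change -1.79, adjusted p = 3.1e-05, named after its value was seen), as did Btg2 (2.17-fold, adjusted p = 2.3e-06), the pro-apoptotic gene Bbc3 (2.38-fold, adjusted p = 2.3e-06) and the kinase gene Plk3 (4.25-fold, adjusted p = 1.3e-05). Trp53inp1, Rrm2b, Fas and Sesn1 rose (log2 fold changes 0.60, 0.47, 0.26 and 0.19, named after their values were seen). Camera did not call the list (adjusted p = 0.141), except as lower on centred TPM (0.0243), and fry called it lower (adjusted p = 0.0025). Fas lost its call without any library but WT replicate 1 (adjusted p = 0.0581 to 0.0975), and Sesn1 without WT replicate 1 or any Abcc4-/- replicate (0.0654 to 0.178). Of 26 apoptosis regulators 4 fell and 2 rose (5 and 2 when adjusted over the list alone; median 0.02, mean -0.13; camera, adjusted p = 0.547; fry lower, adjusted p = 0.0425). Pmaip1 fell 5.63-fold (adjusted p = 0.00028) and Mcl1 by 0.35 on the log2 scale (adjusted p = 0.002), and the survival gene Bcl2l1 rose 1.31-fold (adjusted p = 0.0015). Bcl2 was lower and Casp9 higher, and lost their calls without any library but WT replicate 1 (0.0789 to 0.127) and without WT replicate 2 or Abcc4-/- replicate 2 or 3 (0.0647 to 0.127). Mcl1, Bcl2 and Casp9 were named after their values were seen, and 5 p53 list genes and 4 apoptosis genes are in other lists. Rrm2b, Fas, Sesn1, Bcl2 and Casp9 lost their calls on at least 1 TPM scale (adjusted p = 0.0557 to 0.313), and Bcl2 with at least 1 other count test, scaling, depth or filter (0.0589 to 0.0661).

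In the unfolded protein and integrated stress response list 6 of 28 genes fell and 1 rose (7 and 1 when adjusted over the list alone; mean log2 fold change -0.13, median 0.00029; camera, adjusted p = 0.190; fry, adjusted p = 0.104). The list passed as lower without WT replicate 3 (adjusted p = 0.0498), on log2(TPM + 1) (0.0327) and on centred TPM (0.0294). Atf4, which drives the integrated stress response, fell 1.66-fold (368 ± 11.9 to 222 ± 15.7 CPM, adjusted p = 2e-05), Ddit3 2.09-fold (adjusted p = 7.5e-05) and Dnajc3 1.28-fold (adjusted p = 0.00041), while the asparagine synthetase gene Asns rose (log2 fold change 0.53, adjusted p = 0.0039, picked after its value was seen). Of 36 interferon-stimulated genes Mx1, Ifit2 and Mx2 fell and 0 rose (1 fell when adjusted over the list alone; camera, adjusted p = 0.547). Mx1 lost its call without Abcc4-/- replicate 1 (adjusted p = 0.0549), Ifit2 without any library but WT replicate 2 and Abcc4-/- replicate 2 (0.0535 to 0.0966) and on centred TPM (0.0821), and Mx2 without any library but WT replicate 2 (0.0691 to 0.138).

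Of 25 cholesterol synthesis genes 4 rose and 0 fell (8 and 1 when adjusted over the list alone; median log2 fold change 0.11; camera, adjusted p = 0.0237; adjusted p = 0.652 with an estimated correlation; fry, adjusted p = 0.0995). The sterol oxidase gene Msmo1 rose 1.45-fold (22.7 ± 0.572 to 32.9 ± 3.11 CPM, adjusted p = 0.00046), Hmgcs1 1.23-fold and Hsd17b7 1.32-fold (adjusted p = 0.0046 and 0.009). Acat2, named after its value was seen, lost its call without WT replicate 1 or 2 or Abcc4-/- replicate 1 (0.050 to 0.0672), and the list without Abcc4-/- replicate 1 (0.0653) and on centred TPM (0.0559). Of 35 nuclear genes of oxidative phosphorylation Ndufa5 rose and 0 fell (0 of either when adjusted over the list alone, where 33 of 35 lay above 0; median 0.09; camera, adjusted p = 0.0032; adjusted p = 0.730 with an estimated correlation; fry, adjusted p = 0.275). That list lost its call without WT replicate 3 (adjusted p = 0.0989), and Ndufa5 without any library but Abcc4-/- replicate 3 (0.0652 to 0.144). Of 13 mitochondrially encoded mRNAs mt-Nd1, mt-Nd6, mt-Cytb and mt-Co1 rose and 0 fell (6 rose when adjusted over the list alone; median 0.21; camera, adjusted p = 0.0069; adjusted p = 0.568 with an estimated correlation; fry, adjusted p = 0.0968), and each of the 4 lost its call without some libraries (0.0563 to 0.120). These were WT replicate 1 and Abcc4-/- replicate 1 for mt-Nd1, WT replicate 3 and Abcc4-/- replicates 1 and 2 for mt-Nd6, any but WT replicates 2 and 3 for mt-Cytb, and any but WT replicate 3 for mt-Co1. Hmgcs1, Hsd17b7, Acat2, Ndufa5, mt-Nd1, mt-Cytb and mt-Co1 lost their calls on at least 1 TPM scale (adjusted p = 0.0561 to 0.177), and Ndufa5 with at least 1 other count test, scaling, depth or filter (0.0513 to 0.0922). Mitochondrial genes took 1.65 ± 0.181% of the counts in WT and 1.95 ± 0.0212% in Abcc4-/- (exact p = 0.1). Nuclear copies of them can share reads, so these values are uncertain, and mt-Co1 was named after its value was seen.

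Of 33 glycolysis and hypoxia genes 4 rose and 3 fell (4 and 4 when adjusted over the list alone; median log2 fold change 0.04, -0.04 on log2(TPM + 1) and 0.04 on centred TPM; camera, adjusted p = 0.526). The vascular growth factor gene Vegfa fell 1.74-fold (adjusted p = 0.00042), and Pfkfb4 and Ldha rose 1.25-fold and 1.19-fold (adjusted p = 0.01 and 0.0128). Pgk1, Slc2a3, Egln3 and Ndrg1 were named after their values were seen, and these 4 and Ldha lost their calls without some libraries (adjusted p = 0.0523 to 0.140). These were Abcc4-/- replicate 1 for Ldha, WT replicate 3 and Abcc4-/- replicates 1 and 2 for Egln3, any but WT replicate 1 for Pgk1, any but WT replicate 2 for Ndrg1, and any but WT replicate 1 and Abcc4-/- replicate 1 for Slc2a3. Pfkfb4, Pgk1, Slc2a3, Egln3 and Ndrg1 lost their calls on at least 1 TPM scale (adjusted p = 0.0502 to 0.311). Of 23 arachidonate and prostaglandin genes 4 fell and 3 rose (4 and 6 when adjusted over the list alone). Ptgs2, Ptger4, Ptger3 and the thromboxane synthase gene Tbxas1 fell, the last pair by 0.71 and 0.35 on the log2 scale (adjusted p = 0.0014 and 0.0064), and Ptgir, Mgll and Alox5 rose. Ptger3, Tbxas1, Mgll and Alox5 were named after their values were seen, and Alox5 lost its call without Abcc4-/- replicate 2 (0.0806) and on both uncentred TPM scales (0.108 to 0.114). The list median was 0.08, its mean -0.14, and its camera direction higher (adjusted p = 0.870) where fry's was lower (adjusted p = 0.276).

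Of 32 Rap1 and integrin signalling genes 3 fell (Itga2b, Itga6 and Rapgef2) and 2 rose (Syk and Pik3cb), with the same counts when adjusted over the list alone (camera, adjusted p = 0.533). Rapgef2 and Pik3cb were named after their values were seen, and all 5 lost their calls without some libraries (adjusted p = 0.0540 to 0.141). These were WT replicate 3 for Itga2b, Abcc4-/- replicates 1 and 2 for Itga6, and any library but WT replicate 2 for Rapgef2, WT replicate 3 for Syk and WT replicate 1 for Pik3cb. Itga6, Rapgef2, Syk and Pik3cb lost their calls on at least 1 TPM scale (adjusted p = 0.0529 to 0.442), and Itga2b and Rapgef2 with at least 1 other count test, scaling, depth or filter (0.0504 to 0.0586). Among 42 ribosomal protein genes 0 passed edgeR's test, also when adjusted over the list alone, and the list did not pass (median log2 fold change -0.03; camera, adjusted p = 0.340; fry, adjusted p = 0.741). Rpl13 had the smallest p (log2 fold change -0.15, adjusted p = 0.182), followed by Rpl3 (-0.09, adjusted p = 0.358). Both passed as lower on the uncentred TPM scales (adjusted p = 0.0190 to 0.0275). The ribosomal list passed as lower without WT replicate 3 (adjusted p = 0.0017) and on log2(TPM + 1) (0.0044).

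Called genes near Abcc4 on chromosome 14 were mostly lower. Of 58 other genes tested within 20 Mb, 14 were called (24.1%, 11 lower and 3 higher) against 17.3% elsewhere (odds ratio 1.52, 95% confidence interval 0.771 to 2.84; Fisher's exact test, two-sided p = 0.165). Within 10 Mb, 9 of 28 were called (odds ratio 2.27, 95% confidence interval 0.903 to 5.27, exact p = 0.0458). The 5 with the smallest adjusted p were all lower: Gm26773, the microRNA host gene Mir17hg (2.04-fold, 11.1 ± 0.254 to 5.46 ± 0.779 CPM, adjusted p = 6.6e-05), the growth factor signalling inhibitor gene Spry2 (1.73-fold, adjusted p = 0.00027), Dnajc3 (1.28-fold, adjusted p = 0.00041) and Tgds (1.31-fold, adjusted p = 0.0014). Gm26773, a long non-coding RNA gene at positions 118107831 to 118117100, had 205 counts over the WT libraries (65 to 73 each) and 4 over the Abcc4-/- libraries (0 to 3 each), a ratio of 79.2 (exact 95% interval 30.5 to 294, counting error only). It overlaps Tgds on the other strand, and the libraries were prepared with a stranded kit.

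**Figure D4:**
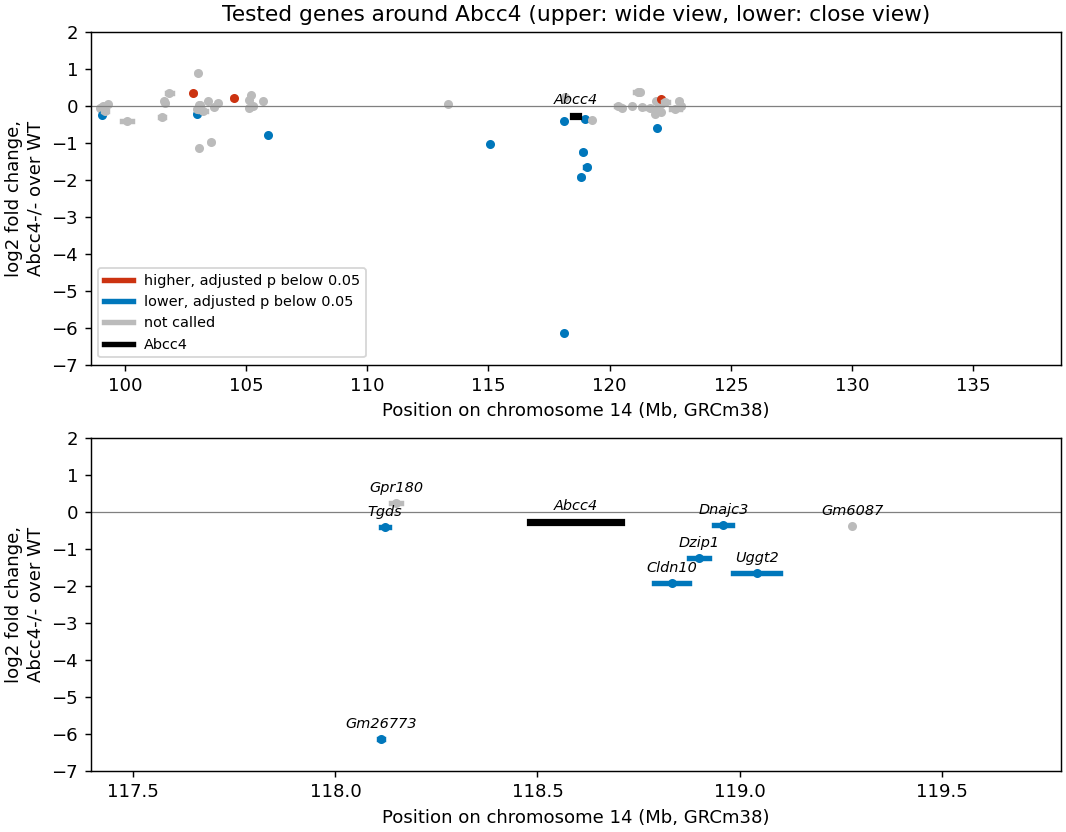
Log2 fold change (Abcc4-/- over WT, y axis) of tested genes by position on chromosome 14 (GRCm38, Mb, x axis), within 20 Mb of Abcc4 above and close to it below. Bars span each gene, red where higher and blue where lower at an adjusted p below 0.05, grey where not called and black for Abcc4, and Gm26773 lies lowest at -6.15.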

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

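Thinning and centred TPM were the tests chosen after the result was seen; the other settings were planned. Other normalizations, filters and count tests called between 2603 and 3284 genes, against 2852, and thinning to the smallest library total 2710, of which 2585 were also called at full depth. On log2(TPM + 1) and log2(TPM + 0.1), 599 and 602 genes were higher, against 1420, and the median of all genes shifted to -0.06 and -0.08. On centred TPM 856 were lower, against 1432; the cause was not tested. Leaving out 1 library gave 1760 to 2415 genes, 823 to 1247 higher and 897 to 1265 lower; these fits have fewer samples. With an estimated correlation 0 lists were called, against 16 (11 by fry, 15 to 18 without 1 library). The 10 Mb window gave an odds ratio of 2.27. On log2(TPM + 1) the transcription factor, mitosis, stress response and ribosomal lists passed as lower (adjusted p = 0.0148, 0.0176, 0.0327 and 0.0044). Chordc1, higher in the count test, was at -0.0083 on both uncentred TPM scales, while its direction did not turn on centred TPM. The replicate block called 3157 genes and 16 lists, but same-numbered libraries did not deviate together (correlations -0.05, -0.03 and -0.01). This gives no sign that the numbers pair the samples, and with few libraries per group it cannot exclude it. Depth limits genes below 0.0302 to 0.0595 CPM.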

Other observations

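The 10 added lists and the tests of time of day, other cell types, megakaryocyte share, depth and the 1 Mb region were chosen after the result was seen. Of 13 early B lymphoid genes 10 rose and 0 fell (11 and 0 when adjusted over the list alone; median log2 fold change 1.26; camera, adjusted p = 3.8e-08; adjusted p = 0.244 with an estimated correlation), among them Dntt, which adds bases to rearranging receptor genes (1.23, adjusted p = 1.8e-06). Of 13 mature B and plasma cell genes Mzb1 and Ighm rose and 0 fell (2 and 1 when adjusted over the list alone; median 0.12; camera, adjusted p = 0.197). Mzb1 lost its call without WT replicate 3 (0.102), and Ighm without WT replicate 1 or Abcc4-/- replicate 1 or 2 (0.0501 to 0.106). Ighm lost its call on each TPM scale (adjusted p = 0.0637 to 0.129), and Mzb1 with at least 1 other count test, scaling, depth or filter (0.0772). Of 13 mature T cell genes 11 rose and 0 fell (11 and 1 when adjusted over the list alone; median 0.90; camera, adjusted p = 6.3e-06; adjusted p = 0.259 with an estimated correlation).

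Of 8 secondary granule genes 6 rose (median 0.51; camera, adjusted p = 3.8e-05; adjusted p = 0.244 with an estimated correlation), and of 10 mature neutrophil genes 6 rose and Ccl6 fell (median 0.64; camera, adjusted p = 0.00051; adjusted p = 0.259 with an estimated correlation). Of 7 primary granule genes Serpinb1a rose and Mpo fell (median -0.02; camera, adjusted p = 0.747), and Mpo lost its call without any library but WT replicate 3 (0.0755 to 0.137) and on centred TPM (0.115); the difference between stages was not tested. Of 14 glucocorticoid-induced genes 7 fell, among them Tsc22d3 (-0.85, adjusted p = 1.1e-05), and Txnip and Il1r2 rose (median -0.40; camera, adjusted p = 0.0111; adjusted p = 0.244 with an estimated correlation). Il1r2 lost its call without Abcc4-/- replicate 1 or 3 (0.0539 to 0.0542) and on each TPM scale (0.110 to 0.426). Of 9 clock genes of the Dbp phase 5 fell and 0 rose (median -0.34; camera, adjusted p = 0.0004; adjusted p = 0.244 with an estimated correlation), and of 5 of the Arntl phase 2 rose, Arntl among them, while Nfil3 and Clock fell (median 0.12; camera, adjusted p = 0.669). Clock lost its call on log2(TPM + 1) (0.0561), log2(TPM + 0.1) (0.0547) and centred TPM (0.0802). Of 16 heat shock genes 3 fell and 1 rose (camera, adjusted p = 0.505).

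The edgeR test called 2852 genes in the real split of the 6 libraries and 0 in each of the others, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each of the others mixed the genotypes in both of its groups. Part of the genotype difference then lay between the groups, and part added to the spread within them. The 0 calls and the list counts therefore do not measure chance alone. Lists behaved differently: the real split called 16 and the highest other 17, and 3 of 10 splits called at least 16. For the DNA replication, oxidative phosphorylation, cholesterol, mitochondrial, erythroid, mast cell and eosinophil lists another split gave a smaller adjusted p than the real one. The same held for the lists not called in the real split, except the p53 list (camera, adjusted p = 0.141 and 0.320). It was 0.340 and 2.1e-18 for ribosomal proteins, 0.0667 and 1.0e-10 for mitosis and 0.547 and 2.6e-09 for interferon-stimulated genes. Camera with the preset correlation can thus give very small adjusted p to lists that did not pass between the genotypes. For immediate early genes the real split gave 3e-23 and the smallest other 2.6e-05, and 8 of the other splits called the list.

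The lower immediate early and NF-kB genes may reflect cell handling, time of day, cell composition or genotype. Against heat-shock-type stress that was stronger in WT and moved the whole list, the heat shock list had a median log2 fold change of -0.050 (95% bootstrap interval over 16 genes -0.23 to 0.16). Of its members 9 were lower and 7 higher. Dnajb1 (-0.48), Bag3 (-0.67) and Dnaja1 (-0.35) fell, and Hspa1a had the largest decrease without passing (-0.76, edgeR adjusted p = 0.156). Chordc1 rose (0.20), but lost its call without any library but WT and Abcc4-/- replicate 3 (0.0631 to 0.105). Stress that moved only some of these genes stays open. Time of day stays open: clock genes of opposite phase lay 0.46 apart (-0.68 to 1.83), with Per1 (-2.38), which is also in the immediate early and glucocorticoid lists, and Ciart (-2.19) lower and Arntl (0.48) higher, but Nfil3 (-1.03) and Clock (-0.35) of the Arntl phase lower, and Dbp (-0.18), Tef (-0.09) and Per2 (0.08) not passing. The median of the immediate early genes lay 0.93 below that of the lowest marker list (0.50 to 1.44), which met the bound set against a lower share of a listed cell type. But markers that other cells also make can dilute a list median, and the bootstrap treated genes as independent. Single members reached -2.41 in the platelet list (median -0.47) and -1.91 in the monocyte list (median -0.12). A lower share therefore stays open for immediate early genes, as for NF-kB genes (0.46, -0.46 to 1.09). The bound of 0 in this test was set after an earlier bound and the result had been seen. The labels do not give handling, harvest or batch, so other handling, harvest and batch cannot be told apart from genotype, which stays open and untested.

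Marker lists of other bone marrow cells could differ through a lower share of megakaryocytes with the makeup of the other cells unchanged, through the greater depth of the Abcc4-/- libraries, or through genotype. The lower share alone would raise the markers of every other cell type, but of the 10 marker lists of other cell types, with megakaryocytes left out, 4 were called lower and 4 higher by camera (3 and 2 by fry), calls of which 0 hold with an estimated correlation. Among the lower lists, the stem list shares Meis1 with the megakaryocyte transcription factors, and the mast cell list shares Il6 and Ccl3 with the NF-kB list, so both are weaker evidence here. The dendritic cell (median -0.28) and eosinophil (-0.57) lists share no gene with the megakaryocyte lists, but fry did not call the eosinophil list (adjusted p = 0.0907). Against depth, 100% of the 8 called marker lists were still called the same way after thinning. A change in the makeup of the other cells stays open, and so does genotype, untested.

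The genes near Abcc4 could be lower through variants carried with the allele, through the deletion itself or by chance placement. Within 20 Mb the planned Fisher's test gave an exact p of 0.165, which met the bound set against flanking variants. Of windows of the same width with at least 50 tested genes, 97.3% held a lower share of called genes, as these variants would predict. But this window held 58 genes, near that minimum, and shares over few genes vary more by chance, so the rank is weak evidence. The odds ratio's interval (0.771 to 2.84) spans an excess as well as none, so flanking variants stay open. Within 1 Mb 6 of 8 genes were called, all lower: Gm26773, Tgds, Cldn10, Dzip1, Dnajc3 and Uggt2. Of these, Gm26773, Cldn10, Dzip1 and Uggt2 were low in WT, with means of 1.28, 0.502, 0.846 and 0.944 CPM. Between Tgds and Cldn10, Gpr180 did not pass (0.25, adjusted p = 0.108), but did as higher with no filter on low counts (0.0305) and without WT replicate 2 (0.0490). A window of 1 Mb was as extreme around 0.521% of 16491 tested genes, and the most extreme of the windows from 0.5 to 20 Mb, 0.5 Mb for Abcc4, around 1.79%, which argues against chance placement. Dzip1 and Uggt2 lost their calls on centred TPM and Uggt2 also on both uncentred TPM scales (adjusted p = 0.148 and 0.170), and an effect of the deletion was not tested.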
